A study of Homo sapiens with 6 samples.

How the data were processed

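MicroRNAs (miRNAs) were measured with 1-colour Agilent miRNA arrays in 6 samples of human periodontal ligament stem cells, the mesenchymal progenitor cells of the tissue that anchors teeth to bone. Total RNA had been labelled with the green dye Cy3 and each sample was hybridised to its own array, per the labels' protocols. Samples were grouped by their titles into 3 control and 3 stretched arrays.

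The labels contradict each other about the treatment. The titles, the series text and the treatment protocol describe cyclic stretch of cells on silicone membranes for 2 h at 5% elongation and 0.5 Hz, against cells left at rest. The source names, the descriptions and the treatment characteristic of the same arrays instead name nicotine for 72 h, at 0 µM for the control arrays and 0.5 µM for the arrays titled stretched. Both readings divide the 6 arrays in the same way, so every value below is a difference between arrays titled stretched and arrays titled control, and the word stretched carries no more than that title. The labels give no separate culture or donor for each array. The p-values therefore measure only the spread between these samples, which may be technical. Each group lay on a slide of its own with its own scan, so slide, scan and group cannot be told apart.

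The scanner files were made with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes and the file headers. The deposited values used here are spot intensities on a linear scale: per the file headers, the processed intensity is the spot signal after background subtraction, not scaled between arrays, and can be negative. Each array held 56044 features, 53880 of them non-control, with 10 to 40 spots per probe, 3101 probes for 1205 human miRNAs and entries for 142 viral miRNAs. The authors' deposited value table equalled the processed intensity on 100% of the values, within a tolerance of 0.5% for rounding to 3 significant digits. It is therefore background-subtracted intensity on the linear scale with no centring and with no change of direction. Its column medians were 0.852, 0.6685 and 1.22 for control replicates 1, 2 and 3 and 0.859, 1.01 and 1.25 for stretched replicates 1, 2 and 3. No step after Feature Extraction is given in the sources used here.

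For the analysis, control spots and outlier spots were left out. The outlier spots made up 3.71% to 5.47% of the non-control spots per array, and no spot was saturated. The processed intensity was divided by each array's 75th percentile over the probes detected on all 6 arrays, floored at a scaled signal of 0.0715 (log2 value of -3.81), and taken to log2, and the spots of a probe were averaged. The floor was the median over arrays of the lowest scaled signal among spots well above background. A probe counted as detected on an array where at least 50% of its spots were well above background. A miRNA's value was the mean of its probes detected on all arrays of at least 1 group, with at most 2 such probes per miRNA. This left 185 human miRNAs for testing. Among the 109 miRNAs with 2 probes, the probes' changes correlated across miRNAs with r = 0.84 and rho = 0.895, where miRNAs are not independent replicates. In 9 of them the probes had opposite signs, and 1 of those 9 passed the threshold. Where both probes count but 1 lies near the floor, the mean understates the change.

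Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, group as the only term), with Benjamini-Hochberg adjustment over the 185 miRNAs and a threshold of 0.05 on the adjusted p. A miRNA not well above background on any array of a group has only a bound there, and its fold is given as at least the stated value. That bound sets the brighter group's mean against, per array, the higher of the dim signal and the lowest signal among probes well above background. Lists of miRNAs fixed before the data were examined were tested with limma's camera at its preset correlation of 0.01, for lists with at least 3 tested members, with Benjamini-Hochberg adjustment over 13 lists. Camera with an estimated correlation and limma's fry were run beside it. Values per array were compared with exact two-sided permutation tests over all 10 splits of the 6 arrays, for which the smallest possible p is 0.1. On simulated data for the comparison of stretched with control arrays (185 miRNAs, 40 of them changed, 50 simulations), the fit recovered 36% of log2 changes of 0.125, 93.2% of changes of 0.25 and 100% of changes of 0.5 and 1. Of its calls, 4.49% were false. The simulated noise was independent between miRNAs and held no difference between slides, so this share does not cover such a difference. Figures were drawn with matplotlib 3.10.9.

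The text names miRNAs by a rule fixed before the data were examined: the 12 largest rises and the 12 largest falls among calls whose arrays do not overlap between groups, up to 4 tested members with the smallest p from each list, and miR-21, miR-29a, miR-29b, miR-29c, miR-145, miR-195, miR-424, miR-18b and miR-1305. It took in 59 tested miRNAs. Names are those of the array's design, which are old and mark the minor strand of a hairpin with a star, and are printed without their species prefix. A gene table for GRCh38.p14 served to find which miRNA genes neighbour each other. Of the tested miRNAs, 150 matched 1 locus in it, 22 several and 13 none. The array's design file names an earlier human build, so no coordinates are given. No probe or miRNA sequences were used here, so GC content was not measured.

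Alternatives covered the percentile over all non-control probes, quantile normalization, no scaling, the median of detected probes, normexp background correction with an offset of 50, Agilent's total gene signal, the brightest probe, the deposited value table, stricter and no detection filters, a moderated fit with trend and robust settings, the replicate number as a block, and leaving out each array. The normexp and unsubtracted alternatives used the median spot intensity in place of the mean. Cyclic loess between arrays, and a fit of the arrays at slide positions held by both groups, were chosen after seeing the data. The text counts 7 of these settings as scalings. They are the percentile over all non-control probes, quantile normalization, no scaling, the median of detected probes, cyclic loess, normexp and total gene signal. Normexp also changes the background correction, and total gene signal the summary of probes. The files hold no depth as sequencing does, and the number of arrays limits the precision.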

Results

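The miRNA content of human periodontal ligament stem cells was profiled on 6 arrays, 3 from cultures titled control and 3 from cultures titled stretched. The series set out to ask which miRNAs change when these cells are stretched cyclically for 2 h at 5% elongation. The labels of the same 6 arrays also name a nicotine treatment (0 µM for control, 0.5 µM for stretched, 72 h), so the treatment behind the difference is not settled by the labels, although the division into groups is. Between 8.96% and 12.4% of the spots of an array were well above background. Human miRNAs were detected in numbers of 163, 153 and 160 on the control arrays and 185, 184 and 197 on the stretched arrays. The log2 profiles of the 185 tested miRNAs correlated across miRNAs at 0.998 to 0.999 within groups and at 0.962 to 0.969 between groups.

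In the main setting, the arrays titled stretched and control differed in most of the tested miRNAs. Of the 139 calls, 47 held under all 7 scalings tried, and slide and group cannot be told apart. miR-146a, which is induced by NF-kB and dampens interleukin-1 and Toll-like receptor signalling, was 2.60-fold higher in stretched cells (log2 change 1.38 ± 0.05, SE, n = 3 per group, limma adjusted p = 1.28e-07). miR-155, a miRNA of inflammatory activation, was 3.25-fold lower (log2 change -1.70 ± 0.05, adjusted p = 1.28e-07). miR-20a and miR-17, members of the proliferation-linked miR-17-92 family, fell by 1.12 ± 0.04 and 0.81 ± 0.04 on the log2 scale. miR-424 and miR-15b, which restrain entry into the cell cycle from G1, fell by 1.05 ± 0.04 and 0.92 ± 0.04. miR-24, an abundant miRNA of the miR-23/27/24 clusters, rose by 0.61 ± 0.04, and miR-21, among the brightest miRNAs in both groups, rose by 0.32 ± 0.05.

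Of the 185 tested miRNAs, 139 passed an adjusted p of 0.05 (75.1%), of which 81 were higher and 58 lower in stretched cells. These counts include miR-188-5p, miR-3132, miR-3659 and miR-3679-5p (higher) and miR-34c-5p (lower), the first 4 named here for that reason alone. They were detected on no control array and their bounds left no difference, so the direction of these calls is not established. The fall of miR-940, named here for a like reason, is not established either. It was detected on 1 control and 3 stretched arrays, with means of -3.57 and -3.76 near the floor. The arrays of the groups did not overlap for 147 miRNAs (79.5%, against 10% by chance without a filter). The 10% does not allow for the detection filter. That filter let in miRNAs well above background on all arrays of only 1 group, 20 of them on no control array. Changes above 2-fold were few: 4 higher (miR-630, miR-146a, miR-1973 and miR-638) and 4 lower (miR-155, miR-20a, miR-193a-3p and miR-424). At 1.5-fold, 17 were higher and 21 lower. miR-630 and miR-1973 were not well above background on any control array, and were at least 4.38-fold and at least 2.17-fold higher in stretched cells. Of the other large rises, miR-638 was 2.52-fold, miR-2861 1.99-fold and miR-30a 1.89-fold higher, followed by miR-431 (1.68-fold), miR-1202 (1.66-fold), miR-26b (1.65-fold), miR-376a* (1.64-fold), miR-1268 (1.62-fold) and miR-150* (1.61-fold). miR-376a* and miR-150* were detected on 2 of the 3 control arrays, and the calls of miR-1202, miR-376a* and miR-150* ended with normexp (0.08, 0.07 and 0.04 on the log2 scale). The large falls also took in miR-193a-3p (2.13-fold), miR-106b (1.80-fold), miR-324-5p (1.76-fold), miR-93 (1.72-fold) and miR-1290 (1.68-fold), and miR-503, which has no exact fold because its stretched values lay at the floor. The SE of these large changes lay between 0.04 and 0.09 on the log2 scale, except 0.17 for miR-1290. Without control replicate 2 the fall of miR-193a-3p was -0.67 on the log2 scale instead of -1.09, because a second probe then entered its mean. By its brightest probe alone miR-146a rose by 2.50 on the log2 scale, since its other probe lay near the floor, and miR-2861 by 1.52. Sizes near background depended on its treatment: the rise of miR-146a was 2.95 with Agilent's total gene signal and 0.69 with normexp, whose added offset shrinks changes of dim probes and left miR-155 at -0.88.

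**Figure D1:**
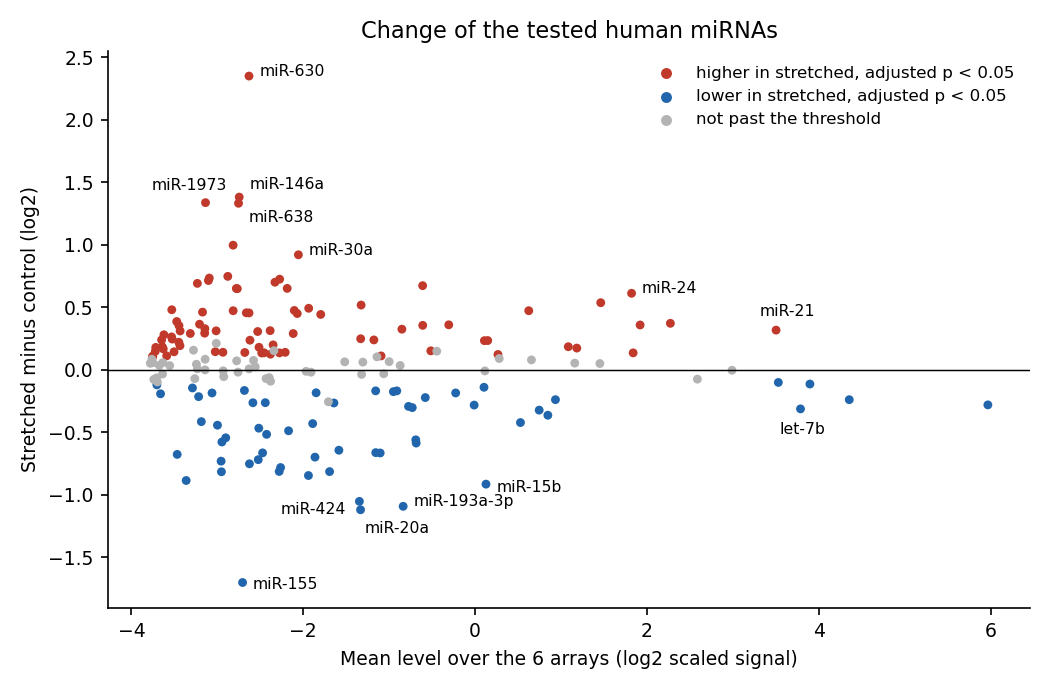
Log2 change (stretched minus control, y axis) of each of the 185 tested human miRNAs against its mean log2 scaled signal over the 6 arrays (x axis), with 1 point per miRNA, red for the 81 higher and blue for the 58 lower in stretched cells at an adjusted p of 0.05. miR-630 lies highest, with its control values at the floor, and miR-155 lowest at -1.70; small changes move across 0 with the scaling, and 79 of the 139 calls keep their sign under all 7 scalings.

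The stretched arrays were brighter over the detected probes and detected more miRNAs. The mean number of detected human miRNAs was 189 ± 7.23 (SD, n = 3) on stretched and 159 ± 5.13 on control arrays, and the 75th percentile of the signal of detected probes was 414 ± 49.9 against 318 ± 18.7 intensity units, 1.30 times higher. Both differences had an exact permutation p of 0.1, the smallest that 3 arrays against 3 can give. Over all non-control probes, most of whose spots were not well above background, the 75th percentile was only 0.117 intensity units higher. The balance of rises and falls differed with the scaling, the background correction and the summary of probes. With the percentile over all non-control probes 114 miRNAs were higher and 23 lower, without scaling 123 and 20, with Agilent's total gene signal 127 and 28, and with normexp 30 and 93. Among the 149 miRNAs detected on all 6 arrays, tested alone, 58 were higher and 57 lower. These scaling and background settings moved the median change of all tested miRNAs, which was 0.06, to 0.34, 0.40, 0.40 and -0.11, and relative to that median 136, 135, 134 and 126 of the 139 calls kept their side. With their plain sign, 47 calls (27 higher, 20 lower) passed the threshold in the same direction under all 7 scalings tried, and the lists below are described with that count. These 7 include normexp and total gene signal, so a call lost there need not depend on the scaling between arrays.

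In the miR-17-92 family, whose members promote proliferation, all 8 tested members fell (0 rose), with a median log2 change of -0.75, and these 8 calls held under the 7 scalings. The named members besides miR-20a and miR-17 were miR-106b (-0.85 ± 0.04), miR-93 (-0.78 ± 0.04) and miR-19b (-0.66 ± 0.03). Camera gave the list an adjusted p of 1.88e-05, and an adjusted p of 0.196 with an estimated correlation. In the miR-15/16 family, 5 of 6 tested members fell and the median was -0.74. miR-424, miR-15b and miR-503 (-0.89 ± 0.04) fell under every scaling, whereas the call of miR-15a (-0.59 ± 0.04) ended without scaling. miR-503 was detected on 1 of the 3 stretched arrays and the floor set the size of its fall, which was -1.63 with Agilent's total gene signal and -0.50 with normexp. miR-195 of the same family had a change of 0.16 ± 0.07 (adjusted p = 0.0778). The family's adjusted p was 0.010 by camera and 0.196 with an estimated correlation, and 0.0649 when only miRNAs detected on all 6 arrays were used.

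All 5 tested members of the miR-23/27/24 clusters rose, with a median of 0.54, and all 5 calls held under the 7 scalings. Probes that bind more than 1 member were not tested for here, and the estimated correlation of the list was 0.731. The 5 rises may therefore not be separate. miR-23b rose by 0.67 ± 0.06, miR-24 by 0.61 ± 0.04, miR-23a by 0.54 ± 0.04 and miR-27b by 0.47 ± 0.04. The adjusted p was 0.0231 by camera and 0.704 with an estimated correlation. It was 0.0599 without control replicate 2, 0.101 with the percentile over all non-control probes, 0.0756 without scaling and 0.263 with Agilent's total gene signal. In the last 3 of these settings the median change of all tested miRNAs was also higher, as given above. No call of a list held with an estimated correlation, for which 0.196 was the lowest adjusted p of the 13 lists.

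**Figure D2:**
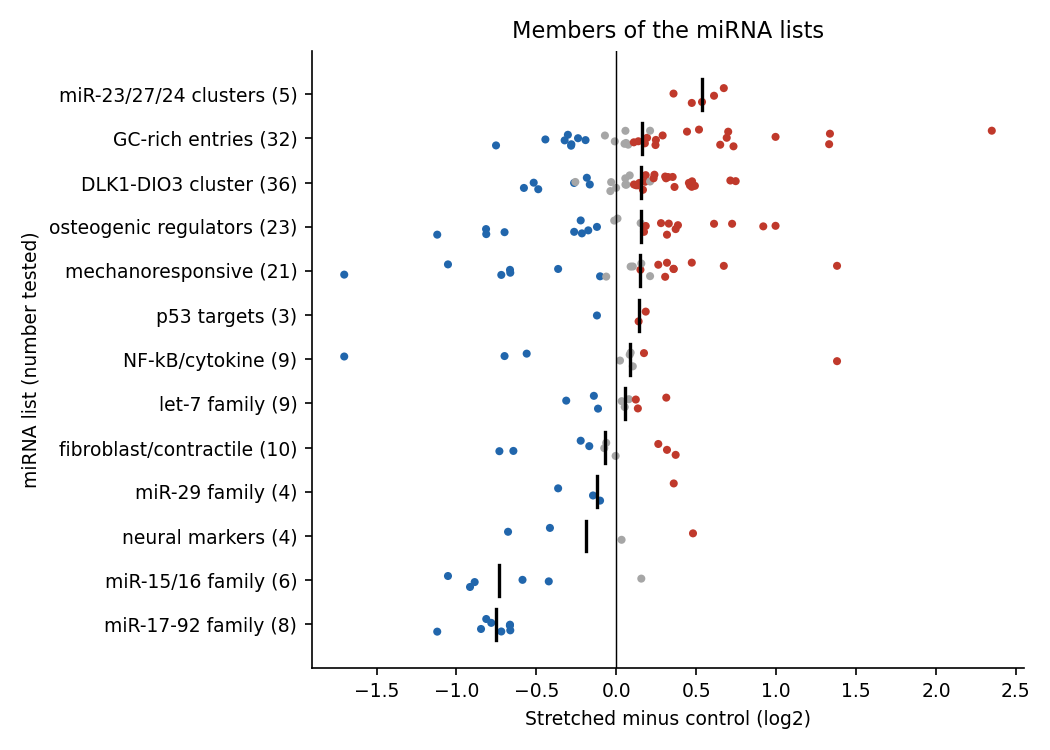
Log2 change (stretched minus control, x axis) of the tested members of 13 miRNA lists (y axis, number tested in brackets), with 1 point per miRNA, coloured red or blue for calls higher or lower at an adjusted p of 0.05 and grey otherwise, and a bar at each list's median. The 8 members of the miR-17-92 family lie to the left of 0 and the 5 members of the miR-23/27/24 clusters to the right under all 7 scalings, while the members of the other lists lie on both sides of 0.

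miRNAs that published work on stretch, compression or flow has measured did not move in one direction. Of 21 tested, 9 rose, 7 fell and 5 did not pass, with a median of 0.15 (-0.04 with normexp) and a mean of -0.02 (camera direction up, adjusted p = 0.990). miR-146a rose and miR-155, miR-424 and miR-19b fell, and 11 of these 16 calls (6 rises, 5 falls) held under all scalings. Within the miR-29 family, which targets collagen mRNAs, miR-29c rose by 0.36 ± 0.04 under every scaling. miR-29b (-0.36 ± 0.09), miR-29a (-0.10 ± 0.03) and miR-29b-1* (-0.15 ± 0.05) fell in the main setting, but each was above 0 without scaling, and these calls of miR-29b, miR-29a and miR-29b-1* ended without control replicate 2, where miR-29a stood at -0.03. The call of miR-29b-1* also ended without each stretched replicate, at -0.09 without stretched replicate 3. The list's camera adjusted p was 0.803 (4 tested, 1 rose, 3 fell), and its median was -0.12, or 0.22 without scaling. Of 10 tested miRNAs abundant in fibroblasts and smooth muscle, 3 rose, 4 fell and 3 did not pass (median -0.07, or 0.31 without scaling, camera adjusted p = 0.621), and 2 rises and 2 falls held under all scalings. miR-22 rose by 0.37 ± 0.04, miR-143 was at least 1.14-fold higher but below 0 with normexp (-0.13), with a change of 0.17 without stretched replicate 2 against 0.26, and miR-199b-5p fell by 0.64 ± 0.04. The change of miR-145, a miRNA of contractile cells, was -0.06 ± 0.05 (adjusted p = 0.315). miR-21 rose whereas miR-21*, from the other strand of its hairpin, fell by 0.73 ± 0.04, both under every scaling. Of 9 tested let-7 members, 3 rose, 3 fell and 3 did not pass (median 0.05, or -0.01 under quantile normalization, camera direction down, adjusted p = 0.990). None of these let-7 calls held under all scalings: let-7b (-0.31 ± 0.05) was above 0 without scaling, and the rises of let-7f (0.13 ± 0.05) and let-7g (0.12 ± 0.04) ended under quantile normalization and without control replicate 3. That of miR-98 (0.31 ± 0.06), of the same family, ended with normexp.

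miRNAs reported to act on osteoblast differentiation went both ways: of 23 tested, 11 rose, 9 fell and 3 did not pass (median 0.15, or 0.11 with the member not above background at its bound and -0.09 with normexp, camera adjusted p = 0.990). The 9 include miR-34c-5p, of which no fall is established, as given below. miR-2861, which represses the histone deacetylase HDAC5 in osteoblasts, and miR-30a rose, while miR-20a and miR-210 fell, and 10 calls (6 rises, 4 falls) held under all scalings. miR-2861 also belongs to the mostly GC-rich list below, whose entries can follow RNA quality or fragments of longer RNA. miR-210, the hypoxia-induced miRNA that formed a list of its own, fell by 0.81 ± 0.06. Among 9 tested miRNAs of NF-kB and cytokine signalling, 2 rose, 3 fell and 4 did not pass (median 0.08, or -0.06 with normexp, mean -0.12, camera direction down, adjusted p = 0.854). There the rise of miR-146a stood against the falls of miR-155, miR-31 (-0.70 ± 0.04) and miR-31* (-0.56 ± 0.04), of which the first 3 held under all scalings. The call of miR-31* ended without scaling (-0.18), and its fall was -0.34 without stretched replicate 1, where a second probe entered its mean. Of 3 tested p53 targets, miR-34a (0.18 ± 0.04) and miR-34b* (0.14 ± 0.05) rose and miR-34c-5p passed with a negative value (median 0.14, or -0.13 with normexp, camera adjusted p = 0.972). None of these p53 target calls held under all scalings, miR-34b* and miR-34c-5p changed sign in some and lost their calls without single arrays, and miR-34c-5p was detected on 0 control and 3 stretched arrays with signals close to the floor, so no fall of it is established.

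Of 36 tested miRNAs of the imprinted DLK1-DIO3 cluster, 21 rose, 6 fell and 9 did not pass, with a median of 0.16, or 0.13 with members not above background at their bound. miR-431 rose by 0.75 ± 0.04, miR-487b by 0.47 ± 0.03 and miR-495 by 0.47 ± 0.03, and miR-299-3p fell by 0.58 ± 0.05. Of these calls miR-431 held under all scalings, whereas those of miR-487b (0.11) and miR-495 (0.08) ended with normexp and that of miR-299-3p (-0.20) without scaling. Relative to the other miRNAs the list did not pass (camera adjusted p = 0.129), while fry, which asks whether its members move on balance one way, gave an adjusted p of 0.00046. Besides the 3 lists called by camera, fry also passed for the lists above of fibroblast miRNAs (adjusted p = 0.00724) and NF-kB miRNAs (0.0176), each toward lower values, and for the mostly GC-rich list below (0.0246). Only 4 calls of the cluster, all rises and miR-431 among them, held under all scalings, and its median was -0.08 with normexp. A list with 47 entries on the array that are often bright on this platform, most of them GC-rich, had 32 tested members, of which 17 rose, 8 fell and 7 did not pass (median 0.16, or -0.05 with normexp, camera adjusted p = 0.335). The 17 include miR-188-5p and miR-3679-5p, of which no rise is established, and the 8 include miR-940, of which no fall is established, as given above. The list held miR-630, miR-1973, miR-638, miR-2861, miR-1202, miR-1268 and miR-150* among the large rises and miR-1290 among the large falls. In the whole list 7 rises and 1 fall held under all scalings, those of miR-1202 and miR-150* not among them. The members that fell included miR-720, an entry since read as a fragment of transfer RNA, and miR-1246, 2 names chosen after their values were seen.

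Markers of other cell types were mostly not detected. No array detected any miRNA of the lists for pluripotent cells (15 on the array), endothelium (2), striated muscle (8), liver (2) or the placental C19MC cluster (37). Of 14 epithelial markers only miR-31 was detected, and it fell, as given above. Of 12 blood cell markers 2 were detected: miR-181a rose by 0.65 ± 0.04, and miR-342-3p had a change of -0.01 ± 0.05. Of 4 tested neural markers, miR-137 was at least 1.23-fold higher, miR-7 was at least 1.59-fold lower, miR-129-3p fell by 0.42 ± 0.06, and miR-128 had a change of 0.03 ± 0.05 (median -0.19, or 0.16 without scaling, camera adjusted p = 0.803). Of these, only the fall of miR-7 held under all scalings. miR-1305 and miR-18b, which published work names in nicotine-exposed periodontal ligament stem cells, were detected on 0 arrays. In every list with a test, the numbers that rose and fell adjusted over the list alone equalled those adjusted over all 185 miRNAs.

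**Figure D3:**
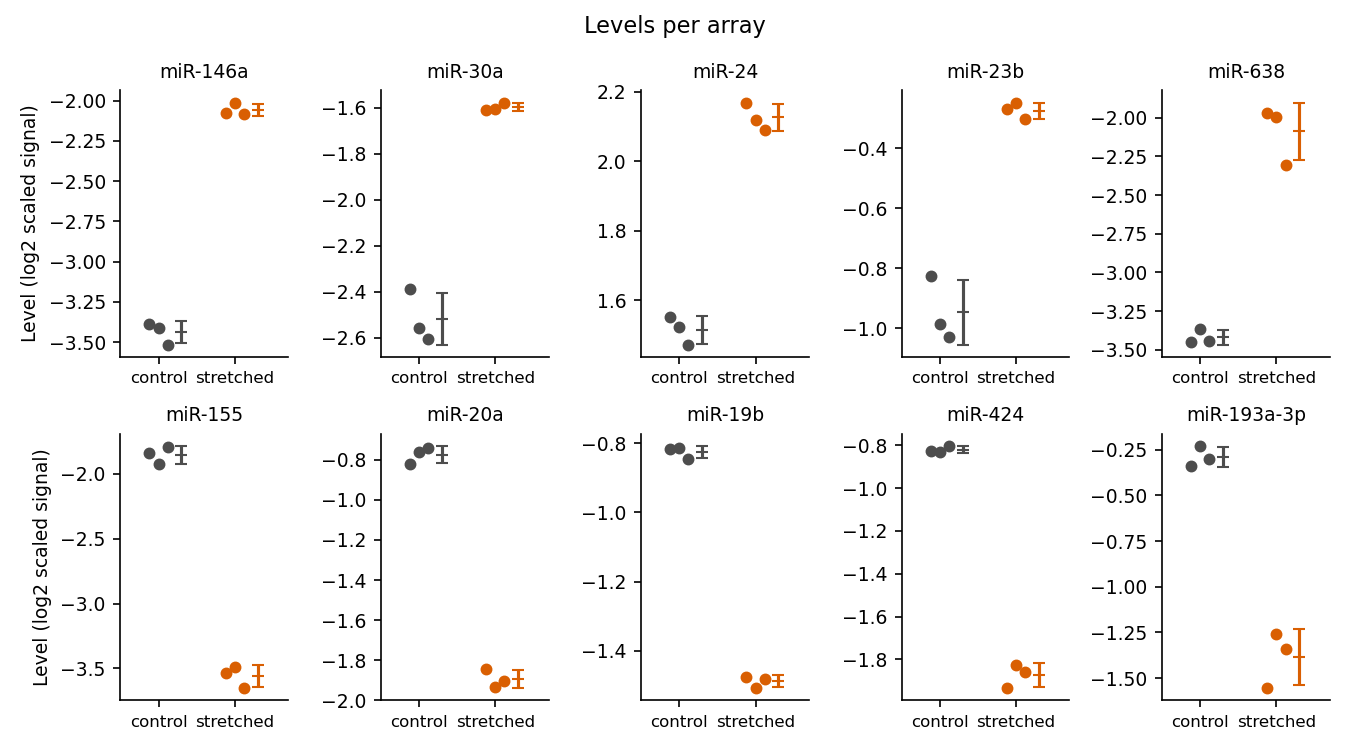
Log2 scaled signal per array (y axis, a separate range in each panel) of 10 named miRNAs in control (grey) and stretched (orange) arrays, with 1 point per array and the mean with its SD (n = 3 per group) beside the points. Control and stretched arrays do not overlap in any panel, the upper row being higher and the lower row lower in stretched cells under all 7 scalings.

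Most called changes were below 1.5-fold but large against the spread between arrays of a group, whose median SD per miRNA was 0.049 in control and 0.0514 in stretched samples on the log2 scale. Each group was hybridised on a slide of its own, and nothing in the labels separates the cultures behind the arrays, so a difference between slides would appear in these values as well.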

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

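The tests of a slide or scan batch, of shared probe binding in the miR-17-92 family and of the entries that are mostly GC-rich were chosen after the results were seen, as was cyclic loess as a setting.

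Probes for viral miRNAs gave signal that differed between the groups, in data outside the main comparison. hsv2-miR-H10 was 0.85 higher in stretched arrays on the log2 scale (detected on 1 of 3 control and 3 of 3 stretched arrays, limma adjusted p = 3.65e-06). kshv-miR-K12-3 was 0.15 higher (detected on all 6). The value of hsv1-miR-H18 was 0.20, but it was detected on 0 control and 3 stretched arrays and its bound was at least 1.00-fold, so no size of a rise is established. In the other direction, hsv2-miR-H24 was -0.23 (adjusted p = 0.0135) and ebv-miR-BART13 -0.22 (adjusted p = 0.0461), both detected on all 6. These values carry no claim of a virus in the cells.

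The pattern of 139 calls among 185 miRNAs was set against 3 technical explanations. A trend of the change with brightness would be removed by cyclic loess, after which 80.6% of the calls (112 of 139) were kept in the same direction, which argues against it as the whole cause. More labelled RNA on the stretched arrays allows no falls without scaling beyond false calls, about 7.15 of 143, but 20 miRNAs were lower there. The bound written beforehand asked for more than 20 and was missed by 1, so the test as written does not exclude the explanation. The 20 falls argue against it as the whole cause only as far as the allowance for false calls holds. That allowance was not part of the bound and takes no difference between slides into account. A slide, scan or labelling batch stays open, since 0 slides held arrays of both groups, and stretch and nicotine, the treatments that the labels name, stay open and untested as causes. As to chance, 1 of the 10 splits of the 6 arrays gave as many calls, the real one (139, highest other 0), and 3 of 10 gave as many lists (real 3, highest other 3); 10 splits are too few for a share under 0.05.

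In the miR-17-92 family all 8 tested members fell. Probes that bind near-identical members could carry 1 fall over to miR-17, miR-20a, miR-93 and miR-106b, but the 4 members of other sequence groups (miR-19a, miR-19b, miR-25 and miR-92a, 3 of them named here after their values were seen) had a median change of -0.67 and each passed the threshold. The falls thus went beyond miR-17, miR-20a, miR-93 and miR-106b, but shared binding among the other 4 was not tested. After cyclic loess the median of the 8 was -0.79, which argues against a brightness trend. The slide batch stays open here as for all calls.

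Entries of the mostly GC-rich list were prominent among the largest rises, and the viral probes bear on them. In the main setting, 8 of 32 tested members (miR-940 included) were lower past the threshold, which argues against one common gain of their signal there. Of those 8 calls only that of miR-1290 held under all scalings, and its control SD was 0.415. The result therefore depends on the processing and does not exclude such a gain. The gap between members, from at least 2.13 for miR-630 to -0.75 for miR-1290, shows only that they did not change alike. The list is mixed and GC content was not measured, so a gain that differs between entries is not excluded. RNA fragments or cross-hybridisation that differ between the groups cannot be told apart from a change in these miRNAs. Of the 6 viral miRNAs detected on all arrays of a group, 3 were higher in stretched arrays past the threshold and 2 were lower. Only hsv2-miR-H6 did not pass (limma adjusted p = 0.0622), so viral miRNAs were called no less often than the human ones (75.1%). These 6 are too few to decide.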

How the results depend on the processing

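Across the settings, 1067 of 1170 values of named miRNAs kept their side of the threshold and, where past it, their direction, 72 lost the call, 11 gained one and 20 changed sign with a call on either side. Of 258 list tests 253 kept their side of the threshold, although the medians of lists that were not called changed sign in settings given above. The 5 lost list calls were those of the miR-23/27/24 clusters (4) and the miR-15/16 family (1) given above. Cyclic loess (128 calls) and the arrays at shared slide positions (124 calls), both chosen after seeing the data, are counted with them. Where no cause is given below, the cause was not tested.

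Against 139 calls, 81 higher and 58 lower (58.3% higher), the percentile over all non-control probes gave 23 lower (83.2% higher), quantile normalization 49.2% higher, no scaling 123 higher and 20 lower (86.0% higher), normexp 30 higher and 93 lower (24.4% higher), and Agilent's total gene signal 127 higher and 28 lower (81.9% higher). The 149 miRNAs detected on all 6 arrays gave 115 calls, 58 higher and 57 lower (50.4% higher). The scaling and background settings can move the median of all miRNAs by construction. Testing all 1205 miRNAs gave 77 calls, 41 higher and 36 lower, since more miRNAs were tested and undetected probes entered the means. Leaving out 1 array gave 111 to 136 calls, 59 to 85 higher, 43 to 62 lower, 53.2% to 66.4% higher, and 2 or 3 lists, and 8 named miRNAs crossed the threshold. The gain in detected miRNAs ranged from 25.8 to 32.3 and that in the 75th percentile from 67.6 to 114 without 1 array.

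Sign changes concern small changes. With the percentile over all probes the values were 0.21 for miR-29a, 0.10 for miR-29b-1*, 0.0209 for miR-34c-5p and 0.30 for miR-342-3p. Without scaling they were 0.0123 for miR-29b, 0.27 for miR-29a, 0.16 for miR-29b-1*, 0.0629 for let-7b, 0.0827 for miR-34c-5p, 0.37 for miR-342-3p and 0.31 for miR-145. With normexp they were -0.13 for miR-143, -0.13 for miR-34b*, -0.20 for miR-128 and -0.17 for miR-195. With total gene signal they were 0.16 for miR-29a, 0.32 for miR-29b-1*, 0.10 for miR-34c-5p, 0.28 for miR-342-3p and 0.40 for miR-145.

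Whether the replicate numbers pair the arrays is not settled. The deviations of same-numbered arrays correlated at 0.014, 0.288 and 0.169, all above 0 but low. Of the arrays, 2 of 3 control and 2 of 3 stretched correlated best with their own number, and so few arrays cannot decide it. As a block the replicate numbers gave 141 calls, 136 of them shared with the fit without a block. Signal over background limits the reach: 20 tested miRNAs were detected on no control array and 14 on only 1 or 2.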

Other observations

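The test of the strands of a hairpin was chosen after its result was seen, and the miRNAs in the next paragraph that the naming rule did not cover were chosen after their values were seen.

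Of the 185 tested miRNAs, 46 belonged to no list, and of these 19 rose, 11 fell and 16 did not pass. The 19 include miR-3132 and miR-3659, which were detected on no control array and of which no rise is established. miR-152, which targets the DNA methyltransferase DNMT1, rose by 0.65 ± 0.04 on the log2 scale (1.57-fold), miR-185 by 0.46 ± 0.05 and miR-151-5p by 0.45 ± 0.03. miR-193a-3p and miR-324-5p, given in the report, led the falls, followed by miR-590-5p (-0.54 ± 0.04) and miR-130b (-0.47 ± 0.04). The calls of miR-152 and miR-151-5p held under all 7 scalings, whereas that of miR-185 held under 6 (lowest value 0.04) and those of miR-590-5p and miR-130b under 5 (values nearest 0 of -0.17 and -0.10).

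The strands of 1 hairpin could part company. Of 13 hairpins, those of miR-140, miR-574, miR-31 and miR-221 had no strand difference past a limma adjusted p of 0.05, and the others did. The log2 change of miR-21 exceeded that of miR-21* by 1.05 ± 0.07 (limma adjusted p over 13 hairpins = 2.14e-07), a difference that no scaling by one factor per array can alter. miR-30a exceeded miR-30a* by 0.61 ± 0.07 and miR-324-3p exceeded miR-324-5p by 0.89 ± 0.11, while miR-193a-3p lay below miR-193a-5p (-0.91 ± 0.08) and miR-136 below miR-136* (-0.72 ± 0.08). miR-30a* was detected on only 2 control arrays. Its change reached 1.20 in the scaling where it was highest, and that of miR-30a was at most 1.26 in any, so their gap depends on the processing. The probes of miR-324-3p had opposite signs. Without control replicate 2, where a second probe entered its mean, the change of miR-193a-3p was -0.67 instead of -1.09. The size of its gap to miR-193a-5p therefore depends on the probes used. A change in the amount of the shared precursor would make strands change alike. Over 13 hairpins the mean absolute difference between strands was 0.416 against a median of 0.514 for random pairings (permutation p = 0.138, one-sided), and 10 hairpins had strands of the same sign. A missed p with 13 pairs excludes nothing, so a change of the precursor stays open.

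The changes of miRNAs encoded side by side lay closer together than those of random sets. Outside the miR-17-92, miR-15/16 and miR-23/27/24 lists, 39 of 122 hairpins lay in 7 neighbourhoods with gaps of up to 10 kb, and the mean absolute difference of log2 changes within them was 0.311 against a median of 0.467 when changes were reassigned at random (permutation p = 0.0151, one-sided, 10000 permutations). Without the DLK1-DIO3 neighbourhoods, 5 remained and the permutation p was 0.0286. The test measures distance and not direction, and small changes lie close together whatever their sign. Of these 5, the ranges of miR-34b* and miR-34c-5p (-0.12 to 0.14), miR-99b, let-7e and miR-125a-5p (-0.18 to 0.24) and miR-143 and miR-145 (-0.06 to 0.26) spanned 0. Those of miR-99a and let-7c (-0.14 to -0.07) and of miR-221, miR-221* and miR-222 (0.02 to 0.10) did not. Shared transcription of neighbouring miRNA genes stays a hypothesis, and the range within the large DLK1-DIO3 neighbourhood, from -0.58 to 0.49, shows that neighbours also parted.

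Among the array's own control features, the median signals of hur_1 and hur_2 were 0.815 and 0.724 times as high on stretched as on control arrays (exact permutation p = 0.1 for each, the smallest possible). The control features did not move one way: hur_6 and miRNABrightCorner30 stood at 1.08 times each (exact permutation p = 0.4 and 0.6), and hur_4, hur_5 and mr_1 at 0.850, 0.915 and 0.839 times (p = 0.4, 0.4 and 0.2), while the remaining 6 features had signals near 0.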
